A study of Homo sapiens with 6 samples.

How the data were processed

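The study sequenced RNA of HEK293 cells, of HEK293 cells overexpressing V2R and of cells overexpressing V279del, each without and with AVP (1 ug, 8 hours), in 6 libraries. Per the labels' protocols, RNA was purified with a Qiagen RNeasy Plus mini kit and made into libraries with a SMARTER mRNA-seq kit. Each of the 6 groups held 1 library, taken from the sample titles. Libraries with AVP stood in one deposited table and those without in another, so any batch that follows the tables also follows AVP.

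The deposited values are FPKM per gene and library, per the file headers and names. The submitters' processing notes name the mouse builds GRCm38 and mm10, although the gene identifiers in both tables are human Ensembl identifiers, and human gene names and lengths were used here. The aligner, the counting tool, its use of strand and the annotation were not given in the sources used here. Gene names, coordinates and exon lengths came from GENCODE 29 on GRCh38, which may differ from the authors' annotation. Of 58884 identifiers, 58611 had an annotated length and 58853 a name. The tables held 0 sample columns from outside the series.

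The authors' FPKM values moved in whole steps of 1 read over the gene length. Reads were recovered as FPKM × exon length × library total, whole to within 1e-05 reads: of 29777 genes above 0, 22060 were whole with the annotated length, 7452 with a fitted length, 150 left the multiple open and 115 had no annotated length. The recovered library totals were 18057424 (HEK293), 15890185 (HEK293 with AVP), 19256014 (V2R), 16687197 (V2R with AVP), 21492956 (V279del) and 17775610 (V279del with AVP), and both tables were on one scale. The mitochondrially encoded genes took 10.1% to 13.6% of the reads. Recovered reads served only for 95% counting intervals (exact Poisson for a level, exact binomial for a ratio), for floors of 3 reads and for a filter. No molecular identifiers were given, so intervals and floors cover counting error only.

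Genes were compared as log2((FPKM + 1)/(FPKM + 1)) between 2 single libraries, with a pseudocount of 1, an FPKM of at least 1 in at least one of them and a size rule of 2-fold. With 1 library per group no test was run and no p-value is given. The 9 comparisons were AVP in each background, V279del against V2R, and each receptor against HEK293 with and without AVP. The 3 differences of AVP response used the same rule with a difference of 1 (log2). Overlaps of calls were set against n1 × n2 / N per direction. Comparisons, size rule, lists, named-gene rule and alternatives were fixed before the data were examined.

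In all, 27 gene lists were fixed for vasopressin and cAMP signalling, protein folding stress, growth, metabolism, RNA quality and other cell types. For each, the median over members with FPKM of at least 1 was placed among 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries, and called apart at or below 2.5 or at or above 97.5 percent. The matching did not include GC content. Genes named in the text were, per comparison, the 10 highest and 10 lowest ratios among genes with a symbol and an FPKM of at least 5 in the higher library, list members at least 2-fold different, and AVPR2, NR4A1, CREM, FOS, SIK1, PDE4D, HSPA5, DDIT3 and ATF4. Many of the former were small RNAs and pseudogenes under 500 nt with few reads (in V279del against V2R with AVP, 6 of the 10 highest and 5 of the 10 lowest) and are left unnamed. The same ranking over genes of at least 500 nt and 50 reads was added, and all other genes named were chosen after their values were seen.

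Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and an FPKM of at least 5, libraries rescaled to 1000000 or by median ratio, size rules of 1.5-fold and 4-fold, equal symbols summed, and list means. Added after seeing the data were the 500 nt and 50 reads filter, removal of a GC trend, lists over differences of response and over rescaled libraries, the overlap of receptor effects, and genes outside 2 of the lists in the same 20 bins of GC content. GC content was that of the longest GENCODE 29 transcript, and the trend was a lowess curve with a fraction of 0.3. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

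The steps were tested on simulated data with counting error only, without variation between cultures or preparations. Error rates of the real calls may therefore be higher. Read recovery returned every count for 95.1% of 3746 genes, and for 80.9% of 954 given a wrong length. In a simulation of AVP in V2R cells, 100% of 100 genes raised or lowered 3-fold and 100% of 100 changed 4-fold were called. The changed genes were drawn only from well-expressed genes of at least 500 nt, so these shares do not cover low or short genes. Of 11894 unchanged genes 106 were called, or 0 of 10464 with 500 nt and 50 reads. The ratio interval held 1 for 96.7% of 22118 unchanged genes. Of unchanged lists of 25 genes 3% were called, and of lists raised 1.5-fold 100%. Those lists were random genes, so the 3% does not say how often a real list, whose genes may vary together, is called. With a simulated GC trend 124 of 11951 unchanged genes were called, and 78 once it was removed. In a simulation of the V2R minus HEK293 response, 253 of 12336 unchanged genes were called, or 0 of 10717 with 500 nt and 50 reads.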

Results

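RNA sequencing measured gene expression in 6 libraries of cells labelled HEK293, an established human embryonic kidney cell line. The cells carried no added receptor, the overexpressed vasopressin receptor V2R, or its deletion mutant V279del. V2R is the product of AVPR2 and couples arginine vasopressin (AVP) to cAMP production in the kidney collecting duct. Each background was sequenced without AVP and after 8 hours with 1 ug of AVP, which gave 6 groups of 1 library. With no replicates there was no replicate check, so no difference was tested. Genes are described as higher or lower by size alone, at least 2-fold on the log2(FPKM + 1) scale with an FPKM of at least 1 in 1 of the compared libraries. That scale understates differences of low genes. Library totals recovered from the values ran from 15890185 reads (HEK293 with AVP) to 21492956 (V279del without AVP). Intervals of levels and ratios below are 95% intervals for counting error only. Those of medians over genes are 95% intervals from the ranked values of the member genes. They do not cover variation between libraries.

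AVPR2 (ENSG00000126895, chromosome X, 153902531 to 153907166, plus strand of GRCh38) was read first, as a check of the labels. It was high in both V2R libraries and low in both V279del libraries. Without AVP its FPKM was 15.7 (14.6 to 16.95; 682 reads) in V2R cells and 1.28 (0.982 to 1.64; 62 reads) in V279del cells, a ratio of 12.3 (9.46 to 16.2). With AVP it was 32.4 (30.6 to 34.3; 1217 reads) in V2R cells and 0.949 (0.672 to 1.30; 38 reads) in V279del cells, a ratio of 34.1 (24.7 to 48.4). Within V2R cells the library with AVP had 2.06 times the level without it (1.87 to 2.26). In V279del cells the ratio of the level without AVP to that with AVP was 1.35 (0.887 to 2.08), an interval that holds 1. HEK293 cells without added receptor had 1 AVPR2 read without AVP (FPKM 0.0246) and 0 with AVP, where 3 reads would give 0.0838. Against that floor AVPR2 was at least 386-fold higher in V2R cells and at least 11.3-fold higher in V279del cells with AVP, and 95% lower bounds that count the error of both libraries were 314 and 8.77. Against the 1 read without AVP the ratios were 639.5 (114 to 25297) for V2R and 52.1 (9.01 to 2090) for V279del. The other vasopressin receptors AVPR1A and AVPR1B had 0 reads in all 6 libraries, as did AVP itself, and the oxytocin receptor gene OXTR had 28 to 58.

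**Figure D1:**
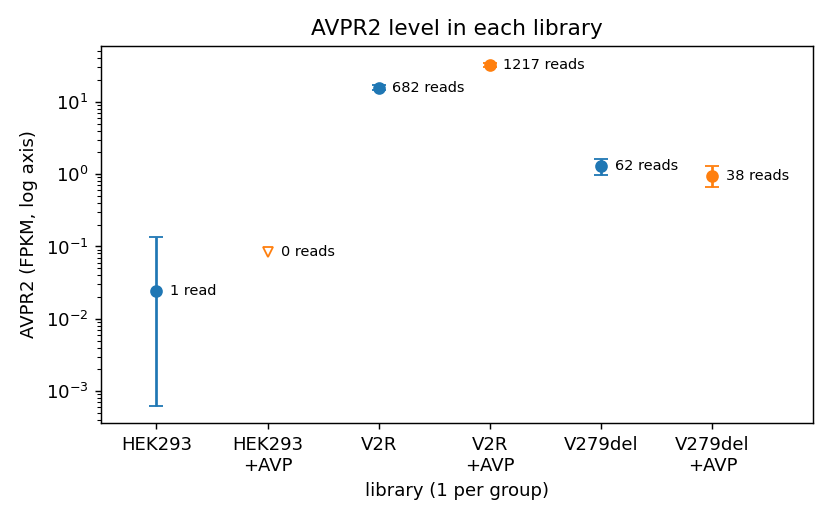
AVPR2 level (FPKM, log axis) in the 6 libraries, 1 point per library with its 95% counting interval and its reads; blue is without AVP and orange with AVP, and the open triangle marks the 3-read floor of a library with 0 reads. The V2R libraries stood at 15.7 and 32.4 and the V279del libraries at 1.28 and 0.949.

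The comparison the series is named for set V279del against V2R cells, both with AVP. Stress genes of the ATF4/CHOP program, which adjusts amino acid supply and protein synthesis under stress, were higher in V279del than in V2R cells. Of 29 measured members, 13 were higher at least 2-fold, 23 at least 1.5-fold and 0 lower. DDIT3, which encodes CHOP, stood at 35.3 against 6.10 FPKM (ratio interval 4.81 to 7.01), and the stress cytokine gene GDF15 at 40.7 against 4.48 (7.70 to 10.8). The phosphatase subunit gene PPP1R15A stood at 20.7 against 3.97, and the cysteine synthesis gene CTH at 54.7 against 13.3. Against HEK293 cells with AVP, the list's median with the GC trend removed was 0.03 in V279del and -0.77 in V2R cells. As a list, these genes were thus low in V2R cells rather than high in V279del cells, although DDIT3 was higher in the latter (log2 1.65). Between V279del and V2R cells with AVP, genes of the endoplasmic reticulum (ER) moved less, and few of them passed 2-fold. HSPA5, the main ER chaperone, had 768 against 296 FPKM (2.56 to 2.64) and HERPUD1, of ER-associated degradation, 100.6 against 35.9.

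The ATF4/CHOP median log2 ratio in that comparison was 0.90 (0.69 to 1.18), above all 10000 random lists matched on expression. ER chaperones and degradation genes had a median of 0.50 (27 members, 9 at least 1.5-fold higher, 0 lower) and cytosolic heat shock genes 0.42 (20 members, 5 at least 1.5-fold higher, 0 lower). Further ATF4/CHOP members that were higher were CHAC1 (log2 1.87), STC2 (1.86), TRIB3 (1.59) and NUPR1 (1.53), while ATF4 itself differed by 0.80. FAM129A (2.57), INHBE (1.83) and PDK4 (1.68), outside the fixed lists, were higher as well. Heat shock genes HSPA1A (1.34) and HSPA1B (1.32) are near-identical copies whose reads could be split, so each value is uncertain. Lower in V279del cells were AVPR2 (-4.10), the immediate early genes FOS (2.49 against 10.9 FPKM, log2 -1.77) and EGR1 (-1.24), the keratin genes KRT8 (-1.47) and KRT18 (-1.05), the collagen gene COL3A1 (-1.41) and the salt transporter gene SLC12A3 (-1.07). Cholesterol biosynthesis genes had a median of -0.34 with 0 of 24 members 2-fold different. Replication-dependent histones (-0.54, 12 members, with reads shared among copies), NF-kB genes (-0.40) and mitochondrially encoded genes (-0.45) were also low as groups, while NRF2 targets and MAPK feedback genes were each at 0.38. With the GC trend removed, the small lists of epithelial (-0.85, 3 members) and fibroblast markers (-0.46, 5 members) lay below the range of random lists too. The fixed cAMP markers NR4A1 (-0.48), CREM (0.43), SIK1 (0.06) and PDE4D (0.08) stayed under 2-fold.

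In V279del against V2R with AVP, 348 genes were higher and 195 lower of 12220, but 243 of the higher and 116 of the lower had under 500 nt of exon. Among genes of at least 500 nt and 50 reads 154 differed, DDIT3, GDF15, CTH and HSPA5 among them. Rescaling each library to 1000000 moved the median of all genes by 0.16 here and by 0.11 in V279del against HEK293 cells with AVP. Under it the medians of the immediate early list (-0.12), glycolysis and hypoxia (-0.09), mitotic (-0.13), YAP/TEAD (-0.11) and nuclear oxidative phosphorylation genes (-0.10) turned to 0.04, 0.04, 0.02, 0.03 and 0.05, and all 5 still lay below the 2.5th percentile of random lists.

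**Figure D2:**
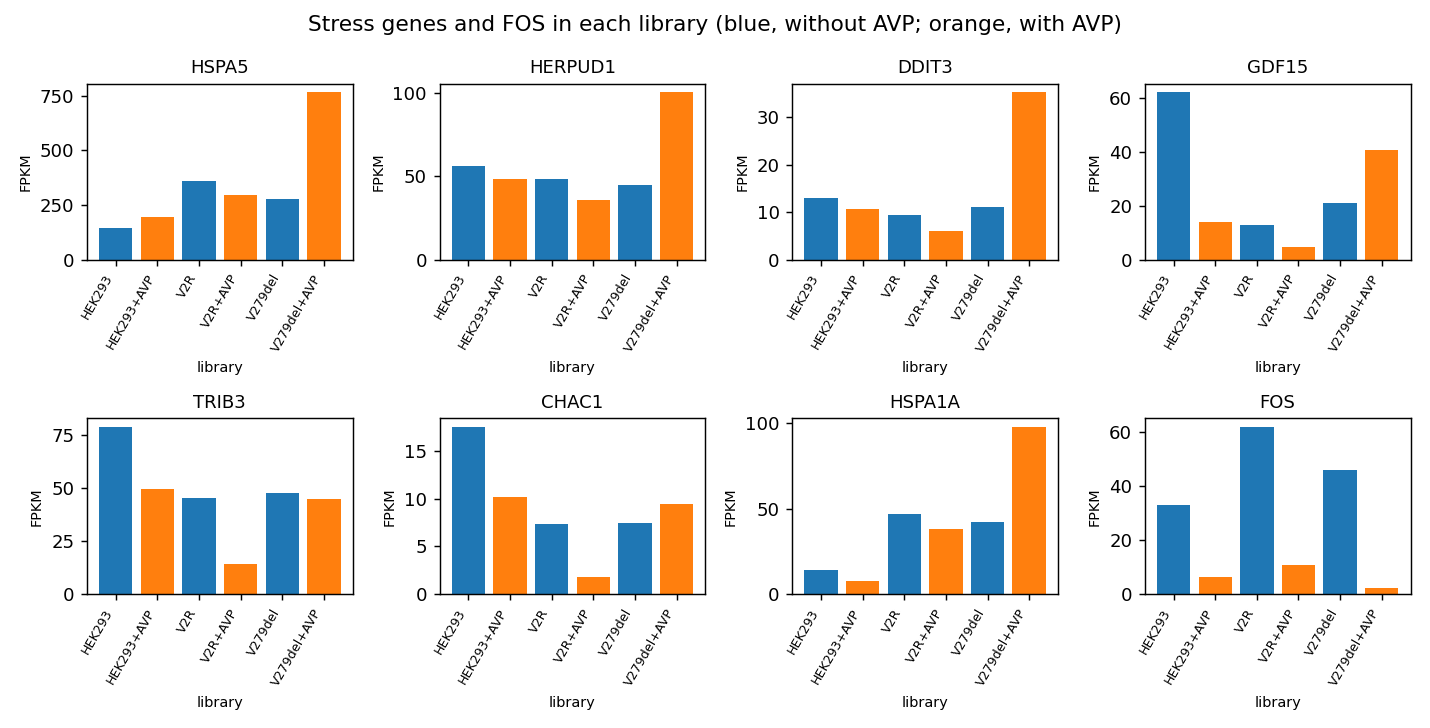
FPKM of 8 genes in the 6 libraries, 1 bar per library from 0 (blue without AVP, orange with AVP; 1 library per group, so no error bars). HSPA5 reached 768, HERPUD1 100.6, DDIT3 35.3 and HSPA1A 97.9 in V279del cells with AVP, their highest levels, while GDF15, TRIB3 and CHAC1 were highest in HEK293 cells without AVP.

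Without AVP, V279del and V2R cells differed in few genes. CA9, a carbonic anhydrase induced by low oxygen, stood at 0.781 FPKM in V279del against 17.5 in V2R cells (ratio interval 0.0291 to 0.0657), and ANGPTL4, a lipoprotein lipase inhibitor, at 0.226 against 5.71. ENO2, a glycolytic enzyme gene, stood at 3.17 against 8.49. Higher in V279del cells were the proteoglycan gene LUM (11.6 against 3.27), the phosphodiesterase gene PDE2A (115 against 55.9) and THBS1 (34.9 against 15.7). ATF4/CHOP genes had a median of 0.11, above the range of random lists, with 0 of 29 members 2-fold different and DDIT3 at 0.22. ER chaperones (-0.04, HSPA5 at -0.38) and heat shock genes (0.05) lay within it. Cholesterol genes (0.32, 24 members), YAP/TEAD targets (0.26) and NRF2 targets (0.26) were high as groups and cytosolic ribosomal protein genes low (-0.34, 49 members, with pseudogene copies), RPL38 at -1.01. Glycolysis and hypoxia genes had a median of -0.21 with 2 of 32 members at least 2-fold lower.

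Of 12200 genes, 125 were higher and 123 lower in V279del than in V2R cells without AVP, with 118 and 103 of them under 500 nt. Among genes of at least 500 nt and 50 reads, 6 were higher and 16 lower.

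AVP in V2R cells set cells with the wild-type receptor with the ligand against those without it. This pair alone cannot assign a change to the receptor, since AVP follows the deposited tables. Of the genes below, MFAP5 (log2 1.97) and FOS (-2.22) also moved with AVP in HEK293 cells without added receptor, while CA9 did not (-0.002). CA9 and ANGPTL4 were highest in the V2R library without AVP. Higher with AVP were the extracellular matrix genes MFAP5 (42.3 against 6.09 FPKM, ratio interval 6.28 to 7.68), LUM (23.4 against 3.27) and FBN1 (15.6 against 4.30), the WNT agonist gene RSPO3 (7.0 against 0.461) and the cell cycle kinase gene CDK6 (13.7 against 2.83). Lower were CA9 (0.447 against 17.5), ANGPTL4 (0.0969 against 5.71), the IGF-binding protein gene IGFBP4 (1.47 against 15.05) and the protease gene PRSS56 (41.1 against 325). Immediate early genes, fast transcriptional responders to stimuli, were lower: 8 of 18 measured members at least 2-fold and 0 higher, with FOS at 10.9 against 61.8 (0.161 to 0.192), EGR1 at 8.44 against 49.5 and JUNB at 21.3 against 107.

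With AVP in V2R cells the immediate early median was -0.87, glycolysis and hypoxia genes had -0.60 (7 of 32 lower, 0 higher) and the ATF4/CHOP list -0.54 (6 of 28 lower, 1 higher), with TRIB3 at -1.60, CHAC1 at -1.56 and the cystine transporter gene SLC7A11 at 1.45. The cAMP/CREB target list, genes switched on by the messenger that V2R raises, had a median of -0.18, within the range of random lists, with 7 of 23 members lower and 0 higher. Its fixed members were at -1.12 (NR4A1), -1.01 (SIK1), 0.11 (CREM) and 0.10 (PDE4D), after 8 hours. HSPA5 was at -0.29, DDIT3 at -0.54 and ATF4 at -0.75. Cholesterol genes had a median of 0.03 with HMGCS1, an early enzyme of the pathway, at 1.13. Mitochondrially encoded genes (0.38) and mitotic genes (0.17) were high as groups, ribosomal protein genes (-0.26) and nuclear oxidative phosphorylation genes (-0.31) low.

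The log2 ratio with AVP in V2R cells followed the GC content of the transcripts (Pearson r -0.68, Spearman rho -0.71, across 12271 genes, which are not independent replicates). With that trend removed, MFAP5 stood at 2.31, RSPO3 at 2.29, LUM at 2.12, AVPR2 at 1.84 (0.997 as deposited), CDK6 at 1.63, CA9 at -3.05, FOS at -2.15, EGR1 at -2.03, IGFBP4 at -1.95, ANGPTL4 at -1.82 and JUNB at -1.40. The immediate early median became -0.64 (8 of 18 lower), glycolysis and hypoxia -0.38 (5 of 32 lower) and ATF4/CHOP -0.25 (1 of 28 lower, 1 higher). The cAMP/CREB median became -0.21 (4 of 23 lower), while cholesterol genes came to 0.28 and heat shock genes to 0.25. The last 3 lists then lay outside the range of random lists, which they did not as deposited. As deposited 251 genes were higher and 848 lower of 12288, and with the trend removed 208 were higher and 219 lower. Exons under 500 nt accounted for 179 of the 251 and 135 of the 848.

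**Figure D3:**
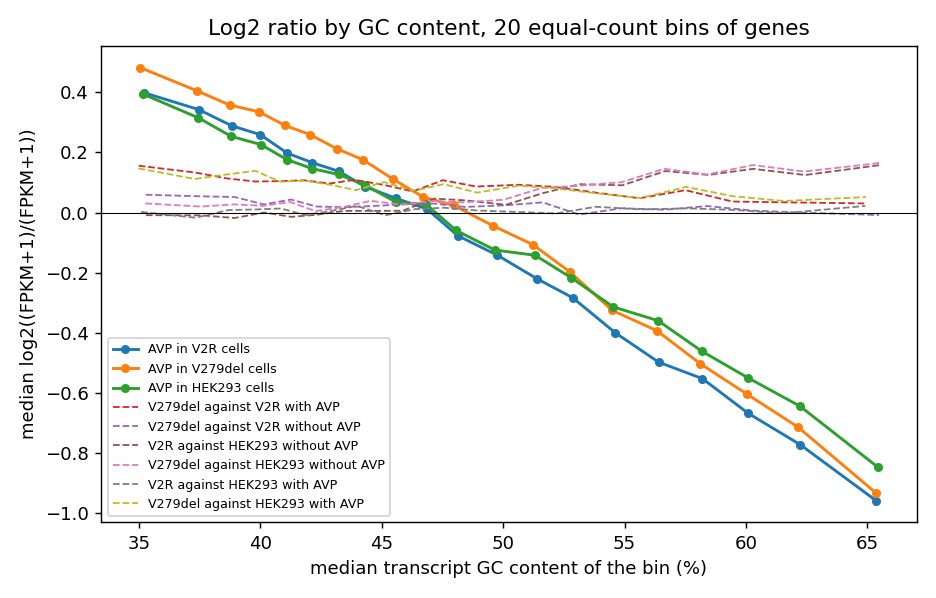
Median log2((FPKM+1)/(FPKM+1)) of genes in 20 equal-count bins of transcript GC content (%), 1 line per comparison; solid lines with points are the 3 comparisons with against without AVP and dashed lines the other 6. The solid lines fell with GC content, with Pearson r of -0.68, -0.65 and -0.64 across genes in V2R, V279del and HEK293 cells.

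AVP in V279del cells came with higher stress and chaperone genes. HSPA5 stood at 768 against 278 FPKM (ratio interval 2.72 to 2.80), DDIT3 at 35.3 against 10.96 (2.82 to 3.68), CTH at 54.7 against 15.03 and PPP1R15A at 20.7 against 7.47. The metabolic kinase gene PDK4 (18.8 against 4.26) and the transcription repressor gene NFIL3 (20.3 against 4.64) were higher too. Lower were FOS (2.49 against 45.9, 0.0455 to 0.0642), EGR1 (2.99 against 32.0), JUNB (11.7 against 72.9), the betaine transporter gene SLC6A12 (1.48 against 19.6), KRT8 (21.1 against 103) and the collecting duct water channel gene AQP3 (7.79 against 37.0).

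By list, AVP in V279del cells went with 7 of 27 ER chaperone and degradation genes higher and 1 lower (median 0.39), among them DNAJB9 (1.23), SEL1L (1.23) and HERPUD1 (1.16). ATF4/CHOP genes had 5 of 29 higher and 2 lower (0.50), and heat shock genes 4 of 20 higher and 0 lower (0.53), HSP90AA1 at 1.06. Lower as groups were immediate early genes (-0.98, 9 of 18 lower), cholesterol genes (-0.67, 7 of 24 lower, DHCR7 at -1.47 and LSS at -1.45), collecting duct transport genes (-0.84, 4 of 9 lower), NF-kB genes (-0.44) and interferon-stimulated genes (-0.41). Histones were at -0.82 with 5 of 13 lower, uncertain because copies share reads. The cAMP/CREB list had a median of 0.08 (7 of 24 lower, 0 higher), with NR4A1 at -1.62, SIK1 at -0.96, CREM at 0.75 and PDE4D at 0.36. ATF4 was at 0.24 and AVPR2 at -0.23.

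GC content ran with the ratio in V279del cells as well (r -0.65, rho -0.68). With the trend removed the medians were 0.62 for ATF4/CHOP (7 of 29 higher, 0 lower), 0.40 for ER genes (3 of 27 higher, 0 lower) and 0.58 for heat shock genes (3 of 20 higher). Those of immediate early genes (-0.63, 5 of 18 lower), cholesterol genes (-0.44, 1 of 24 lower) and histones (-0.85, 4 of 13 lower) stayed below 0. The cAMP/CREB median turned from 0.08 to -0.15 and then lay below the range of random lists, and NF-kB genes came to -0.07, within it. DDIT3 was then at 1.69, HSPA5 at 1.41, CTH at 1.63, FOS at -3.50, EGR1 at -2.65, KRT8 at -1.78 and AQP3 at -1.60. As deposited 366 genes were higher and 845 lower of 12512, 1396 and 1760 with libraries rescaled to 1000000, and 317 and 216 with the GC trend removed. Of the 366 higher, 262 had under 500 nt of exon.

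AVP in HEK293 cells without added receptor served as the background. C8orf4 stood at 92.8 against 15.6 FPKM (ratio interval 5.43 to 6.56), MFAP5 at 39.99 against 9.50 and ID3, an inhibitor of differentiation factors, at 37.5 against 11.2. Lower were the aldose reductase gene AKR1B1 (153 against 808), the metallothionein gene MT2A (27.8 against 134), GDF15 (14.1 against 62.4), the NOTCH target HES1 (7.15 against 36.0) and FOS (6.32 against 33.1). The ferritin gene FTH1, which shares reads with pseudogenes and is uncertain, was at -2.77. Immediate early genes had 9 of 19 lower and 0 higher (median -0.95), and cholesterol genes 5 of 24 lower and 0 higher (-0.66), DHCR7 at -1.58 and LSS at -1.43. ATF4/CHOP genes were at -0.25 (1 of 30 higher, 3 lower), ER chaperones at -0.04, heat shock genes at -0.06, cAMP/CREB targets at -0.12 (1 of 24 higher, 5 lower) and MAPK feedback genes at -0.42. NR4A1 was at -0.60, SIK1 at -1.004, CREM at 0.54, PDE4D at 0.93, HSPA5 at 0.44, DDIT3 at -0.28 and ATF4 at -0.40.

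The GC trend was present in HEK293 cells too (r -0.64, rho -0.69). With it removed, C8orf4 stood at 2.13, ID3 at 2.04, MFAP5 at 1.71, AKR1B1 at -2.17, HES1 at -2.10, FOS at -2.03, MT2A at -1.99 and GDF15 at -1.41. Immediate early genes came to -0.56 (4 of 19 lower), cholesterol genes to -0.50 (4 of 24 lower) and ATF4/CHOP genes to -0.02, within the range of random lists. The fibroblast marker list, with 5 measured members, was at 0.76, above that range. As deposited 263 genes were higher and 530 lower of 12107, of which 52 and 391 had at least 500 nt and 50 reads, and with the trend removed 216 were higher and 185 lower.

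The AVP responses of the 3 backgrounds overlapped. V2R and V279del cells shared 381 lower and 38 higher genes, where independent lists would share 52.3 and 3.0, with r 0.66 and rho 0.68 across genes. Each shared 284 and 286 lower genes with HEK293 cells (30.6 and 31.5 for independent lists), which lacked the receptor, and 213 were lower in all 3. These comparisons share no library. The median GC content of the 213 was 63.7%, against 47.5% of the genes considered in V2R cells. After removal of the trend 23 genes were lower and 8 higher in all 3. FOS, EGR1, JUN, JUNB, HES1, IFI6 and SLC6A12 were among 14 of the 213 that stayed, and the growth factor genes BMP2 (mean 1.31) and BMP6 (1.18) were among the 8.

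The difference of AVP responses, which carried little of the GC trend (r -0.10, -0.11 and -0.02), set the backgrounds apart. In V2R minus HEK293 cells, cholesterol genes were higher (median 0.70, 6 of 24 by at least 1 log2 unit, 0 lower), with HMGCS1 at 1.90 and MSMO1 at 1.72. Much of this was a fall in HEK293 cells. The list's response in V2R cells was 0.03 as deposited. With the GC trend removed it was 0.28 in V2R and -0.50 in HEK293 cells. Several medians lay below the range of random lists, with few members past the size rule. They were those of ATF4/CHOP genes (-0.34, 1 of 30 lower, 0 higher), glycolysis and hypoxia genes (-0.29, 1 of 32 lower, 0 higher) and cAMP/CREB targets (-0.37, 2 of 24 lower, 0 higher, with an interval of -0.53 to 0.04 that holds 0). Ribosomal protein (-0.13), nuclear oxidative phosphorylation (-0.15) and proteasome genes (-0.14) also lay below it, with 0 members past the rule. Between V2R and HEK293 cells the cAMP/CREB median was 0.25 without and -0.13 with AVP, and that of glycolysis and hypoxia genes 0.29 and 0.02. In V279del minus HEK293 cells cAMP/CREB targets were at -0.16 (-0.57 to 0.20; 4 of 24 lower, 0 higher). Among single genes in V2R minus HEK293 cells, the plasminogen activator gene PLAT was at 2.11 and the thrombin receptor gene F2R at 2.07. CA9 was at -3.67, TXNIP at -2.13 and ID3 at -1.80 there. The response of PLAT itself was -0.14 in V2R and -2.25 in HEK293 cells. In V279del minus HEK293 cells, ATF4/CHOP (0.54, 7 of 30 higher, 0 lower), heat shock (0.46, 5 of 20) and ER genes (0.38, 5 of 27) were higher. GDF15 was at 2.99 (responses of 0.92 in V279del and -2.07 in HEK293 cells), PPP1R15A at 2.30 and DDIT3 at 1.88. SLC12A3 was at -2.71 and ID3 at -2.12. In V279del minus V2R cells, ATF4/CHOP (0.80, 10 of 29 higher, 1 lower) and ER genes (0.55, 5 of 27 higher) were higher and cholesterol genes lower (-0.68, 3 of 24 lower), with CTH at 2.34, DDIT3 at 2.14, HSPA5 at 1.75, LUM at -1.98 and KRT8 at -1.60.

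CA9 was also at 3.08 and ANGPTL4 at 2.67 in V279del minus V2R cells, and both were highest in the V2R library without AVP, at 17.5 and 5.71 FPKM. By size, 314 genes were higher and 389 lower in V2R minus HEK293, 412 and 363 in V279del minus HEK293 (387 and 394 with libraries rescaled by median ratio), and 499 and 350 in V279del minus V2R.

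V2R against HEK293 cells without AVP asked how cells with the receptor differ when no ligand is added. Besides AVPR2, higher genes were CA9 (17.5 against 0.276 FPKM), the glycoprotein hormone subunit gene CGA (28.5 against 3.95, ratio interval 6.11 to 8.53), ETNPPL (30.1 against 4.78), ID3 (49.1 against 11.2) and HSPA5 (362 against 143, 2.48 to 2.59). Lower were GDF15 (12.9 against 62.4), PDE2A (55.9 against 222), MT2A (39.8 against 134) and the noncoding RNA LINC01133 (0.658 against 11.5). ATF4/CHOP genes had 8 of 29 lower and 0 higher (median -0.58), with GADD45A at -1.57 and STC2 at -1.47. Heat shock genes (0.54, 2 of 20 higher), ER genes (0.28, 3 of 27 higher, SDF2L1 at 1.63 and MANF at 1.30), glycolysis and hypoxia genes (0.29, 4 of 32 higher) and cAMP/CREB targets (0.25, 2 of 24 higher) were high as groups, and YAP/TEAD targets low (-0.37, ANKRD1 at -2.16). NR4A1 was at 0.72 and FOS at 0.88. Of 12171 genes, 243 were higher and 196 lower, 105 and 99 with at least 500 nt and 50 reads.

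V279del against HEK293 cells without AVP asked the same of the mutant. ID3 stood at 70.4 against 11.2 FPKM (ratio interval 5.57 to 7.10), CGA at 20.02 against 3.95, ETNPPL at 27.2 against 4.78 and the secreted neuronal protein gene OLFM1 at 7.77 against 0.886. MT2A stood at 28.9 against 134, PLAT at 2.49 against 11.4 and GDF15 at 21.1 against 62.4. ATF4/CHOP genes had 4 of 29 lower and 0 higher (-0.52), heat shock genes 2 of 20 higher (0.53), ER genes 1 of 27 higher (0.23, HSPA5 at 0.96) and cholesterol genes a median of 0.29. Histones were at -0.51. Of 12144 genes, 208 were higher and 166 lower, 62 and 66 with at least 500 nt and 50 reads. Both receptor comparisons without AVP share the HEK293 library, and their overlap was not counted.

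With AVP, V2R cells had lower ATF4/CHOP genes than HEK293 cells: 12 of 30 at least 2-fold, 25 at least 1.5-fold and 0 higher (median -0.78). CHAC1 stood at 1.84 against 10.1 FPKM (ratio interval 0.137 to 0.239), CTH at 13.3 against 54.2, TRIB3 at 14.2 against 49.7 and the serine synthesis gene PSAT1 at 76.9 against 175. Cholesterol genes were higher, 5 of 24 at least 2-fold and 0 lower (0.61), with HMGCS1 at 42.7 against 14.99, the sterol sensor gene INSIG1 at 39.9 against 14.8 and MSMO1 at 59.8 against 24.9. Heat shock genes had 4 of 20 higher (0.56, HSPA8 at 501 against 165) and ER genes a median of 0.21. The cAMP/CREB list had a median of -0.13 with 1 of 23 higher, 0 lower and NR4A1 at 0.21. Of 11919 genes, 176 were higher and 202 lower, 23 and 59 with at least 500 nt and 50 reads.

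V279del against HEK293 cells with AVP showed the highest chaperone medians of the 9 comparisons. Heat shock genes had 10 of 20 higher and 0 lower (1.07), with HSPA8 at 605 against 165 FPKM (ratio interval 3.60 to 3.74), HSPH1 at 73.6 against 24.8 and DNAJB1 at 93.8 against 33.7. ER genes had 7 of 27 higher, 17 at least 1.5-fold and 0 lower (0.84), with HSPA5 at 768 against 194 and MANF at 57.0 against 13.8. The ATF4/CHOP list had a median of 0.03, within the range of random lists, with 3 of 30 members higher and 0 lower, DDIT3 at 35.3 against 10.54 among them. Lower were C9orf152 (0.611 against 7.62), the heparan sulfate proteoglycan gene SDC4 (9.45 against 43.6), SLC12A3 (9.17 against 31.9) and KRT8 (21.1 against 60.1). Histones had 8 of 14 lower (-1.07, copies sharing reads), NF-kB genes were at -0.55 and nuclear oxidative phosphorylation genes at -0.08, the last turning to 0.03 with libraries rescaled to 1000000. Of 12250 genes, 372 were higher and 183 lower, 71 and 84 with at least 500 nt and 50 reads.

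The receptor comparisons with and without AVP share no library. V2R against HEK293 cells shared 21 higher and 32 lower genes between them (1.08 and 1.32 for independent lists; r 0.37 across genes), V279del against HEK293 22 and 14 (2.05 and 1.23; r 0.33) and V279del against V2R 18 and 11 (1.08 and 0.829; r 0.08).

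**Figure D4:**
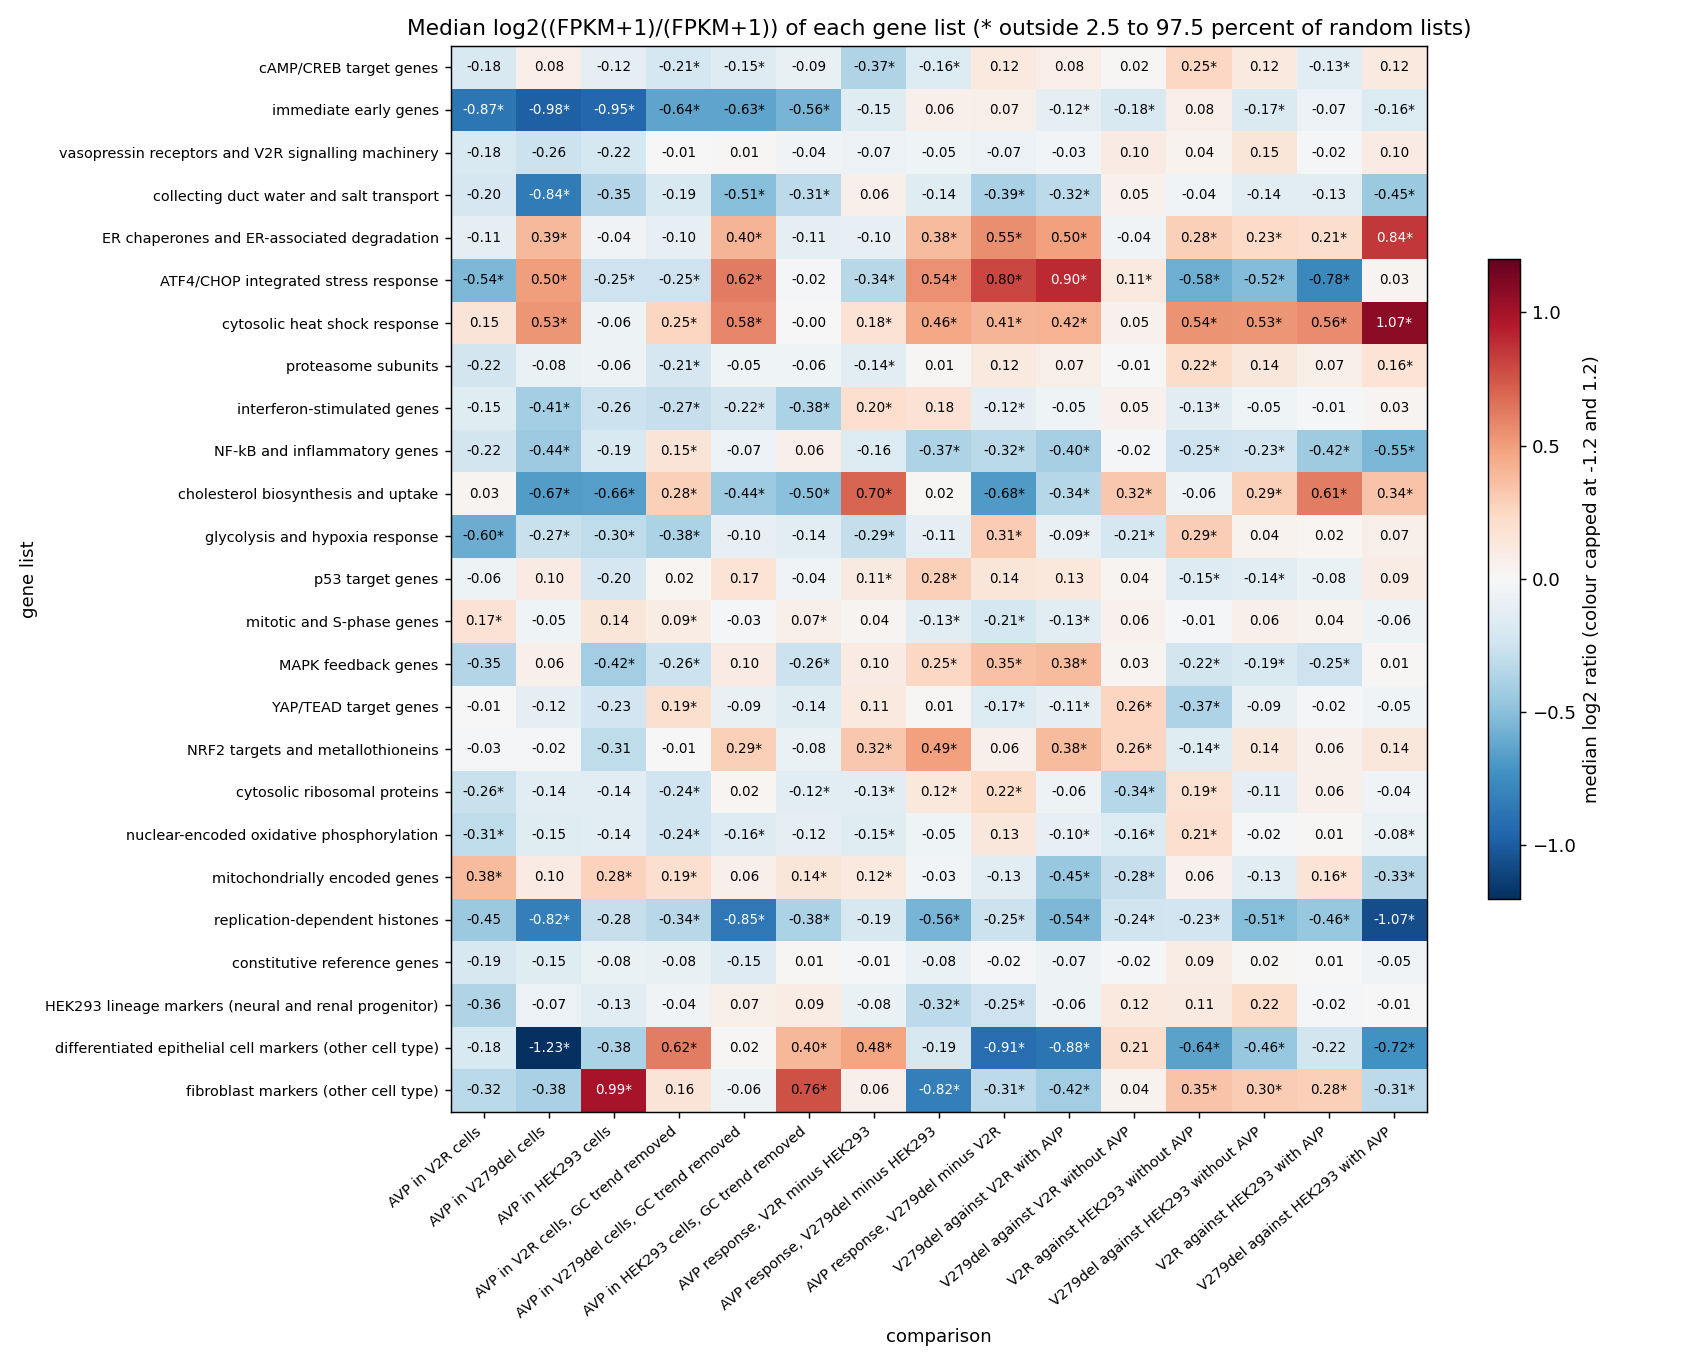
Median log2((FPKM+1)/(FPKM+1)) of each gene list with measured members (rows) in each comparison (columns; the 3 AVP comparisons also with the GC trend removed, and the 3 differences of AVP response), with an asterisk where the median lay outside the central 95% of 10000 random lists. ATF4/CHOP genes ran from -0.78 in V2R against HEK293 cells with AVP to 0.90 in V279del against V2R cells with AVP, where rescaling libraries to 1000000 turned 6 negative medians positive.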

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

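Of the tests in this part, those of a batch, of the mutant without ligand, of genes with the same GC content, of a stress of 1 library, and both of AVPR2 were chosen only after the result was seen. Removal of a GC trend, which other tests here use, was itself added after seeing the data. The 1 result that met a rule for a closer look was the AVP response of ATF4/CHOP genes, whose median was -0.54 in V2R cells and 0.50 in V279del cells. The median over genes of the difference between the responses was 0.80. With the GC trend removed the medians were -0.25 and 0.62. The difference was not tested, since each group had 1 library.

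ATF4/CHOP genes were higher in V279del than in V2R cells with AVP, at a median of 0.90. The ER chaperone median was 0.50, with few members past the size rule (2 of 27 with the GC trend removed). In these single libraries, values without AVP argue against the mutant receptor alone as the main cause. The ATF4/CHOP median without AVP was 12.6% of that with AVP, and the ER median without AVP was not above 0. An upper bound of 26.0% for the former covers only the spread over genes of the median without AVP. It leaves out the error of the median with AVP and any variation between libraries. Removal of the GC trend decides nothing here (98.2% of the ATF4/CHOP median was kept), since there was little trend to remove (r -0.07). Against GC bias, genes outside the lists with the same GC content had medians of 0.09 (ER) and 0.08 (ATF4/CHOP), where all genes had 0.09. With that subtracted on both sides they gave 0.331% (upper bound 0.720%) and -1.14% of the list medians. These values read the same near absence of a trend at the GC content of the members. The upper bound varied only the list median over its genes. What stays open is whether V279del cells respond to AVP or whether the 1 library of V279del cells with AVP was stressed for another reason. The 1 library of V2R cells with AVP, whose ATF4/CHOP genes were low, has the same limit. These cannot be told apart without second libraries. Against HEK293 cells the ATF4/CHOP medians without and with AVP were -0.58 and -0.78 in V2R cells. In V279del cells they were -0.52 and 0.03. V279del cells thus differed more between the conditions, while with AVP the V2R cells lay further from HEK293 cells. Neither was tested.

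In all 3 backgrounds 213 genes were at least 2-fold lower with AVP, with a median GC content of 63.7%. For vasopressin acting through the added receptor, the 378 genes lower in both receptor backgrounds were read in HEK293 cells. Their median there was -1.07 (-1.11 to -1.02), and 98.7% of them had a ratio below 0, of any size. That test decides nothing about the receptor. Most of the 378 were the 213, picked as at least 2-fold lower in HEK293 cells too, which fixed the median. The values also carried the GC trend that all 3 backgrounds shared. A GC bias between libraries with and without AVP is a candidate explanation for part of the pattern. After removal of the trend 6.57% of the 213 (14 genes) stayed 2-fold lower in all 3. The median of the 213 in V2R cells went from -1.36 (-1.40 to -1.30) to -0.56 (-0.61 to -0.52). In V279del and HEK293 cells it was then -0.57 and -0.62. Fewer calls remained because these medians then lay under the 2-fold size. Removal takes away any change that follows GC content, so it cannot tell a bias from a response to AVP. A batch or culture difference cannot be told apart from AVP, since 0 deposited tables or labelled batches held libraries of both kinds, and FOS, EGR1 and JUNB, which stayed, share this limit.

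AVPR2 was lower in V279del than in V2R cells. Reads over the deletion that fail to align would take away a small part of the transcript, whereas the lower bound of the ratio without AVP was 9.46. Lower expression of the mutant construct and a construct sequence that differs from the reference could each give the ratio of 34.1 with AVP and cannot be told apart, since reads were not analysed here. A biological explanation other than these was not tested.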

How the results depend on the processing

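No paired analysis was possible within a background because each group held 1 library and the labels gave no replicate numbers. A fit of AVP over the 3 backgrounds, each with and without it, was not made, since they are different cells rather than replicates. Tests over the 500 nt and 50 reads filter, the removed GC trend, and gene lists over rescaled libraries were chosen only after the result was seen. Of 149 alternative values of comparisons, overlaps and receptor levels, 60 stayed close and 89 moved, by a rule that could not return a reversal. The split of calls did turn in some. With the GC trend removed, AVP in V279del cells went from 366 higher and 845 lower to 317 and 216. AVP in HEK293 cells went from 263 and 530 to 216 and 185. With median-ratio rescaling, V279del minus HEK293 went from 412 and 363 to 387 and 394. Of 1341 list medians 1285 stayed close, 45 moved and 11 reversed. Only lists outside the range of random lists as deposited were counted as reversed. Of 3115 values of named genes 2195 stayed close, 919 moved and 1 reversed. Counts of genes were close under no filter, median-ratio rescaling and summed symbols. Depth limits short genes most: in V2R with AVP the higher genes had a median of 7 reads in the higher library, so counts of higher genes are less firm than those of lower ones.

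Counts of differing genes are given in the order AVP in V2R cells, AVP in V279del cells, AVP in HEK293 cells, V279del against V2R with AVP, V279del against V2R without AVP, V2R against HEK293 without AVP, V279del against HEK293 without AVP, V2R against HEK293 with AVP and V279del against HEK293 with AVP. A pseudocount of 0.1 gave 2072, 2178, 1575, 1095, 558, 901, 790, 791 and 1182. A pseudocount of 5 gave 185, 237, 138, 50, 13, 72, 47, 43 and 58. An FPKM of at least 5 gave 635, 705, 408, 143, 44, 177, 136, 93 and 152, with fewer genes considered. Libraries rescaled to 1000000 gave 2888, 3156, 2355, 2225, 1352, 1629, 1620, 1627 and 2310. Sizes of 1.5-fold gave 3383, 3572, 2642, 1637, 744, 1382, 1230, 1070 and 1787, and of 4-fold 48, 47, 43, 31, 14, 32, 25, 23 and 25. The 500 nt and 50 reads filter gave 443, 154, 22, 204, 128, 82 and 155 from AVP in HEK293 cells onward, and the removed GC trend 427, 533 and 401 for the 3 comparisons with AVP. The low pseudocount and the rescaling weigh low genes more by construction, and the high pseudocount less.

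For the difference of AVP response, V2R minus HEK293, the difference of AVP response, V279del minus HEK293, and the difference of AVP response, V279del minus V2R, a pseudocount of 0.1 gave 1426, 1568 and 1717, a pseudocount of 5 gave 75, 108 and 106, and an FPKM of at least 5 gave 178, 224 and 255. For the overlap of AVP responses (V2R and V279del), then the overlap of AVP responses, V2R and HEK293, the overlap of AVP responses, V279del and HEK293, and the overlap of AVP responses, all 3 backgrounds, a pseudocount of 0.1 gave 828, 727, 701 and 495, a pseudocount of 5 gave 93, 73, 70 and 53, and the removed GC trend 78, 68, 82 and 31. With libraries rescaled to 1000000, the receptor level, V2R was 49.0, the receptor level, V2R_AVP 98.2, the receptor level, V279del 4.25 and the receptor level, V279del_AVP 3.21, since each FPKM sum was under 1000000.

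Some list medians changed sign. With libraries rescaled to 1000000, these were gene list immediate early genes, V279del against V2R with AVP (0.0377), gene list glycolysis and hypoxia response, V279del against V2R with AVP (0.0388), gene list mitotic and S-phase genes, V279del against V2R with AVP (0.0210), gene list YAP/TEAD target genes, V279del against V2R with AVP (0.0327), gene list nuclear-encoded oxidative phosphorylation, V279del against V2R with AVP (0.0527) and gene list differentiated epithelial cell markers (other cell type), V279del against V2R with AVP (0.0783). Likewise gene list nuclear-encoded oxidative phosphorylation, V279del against HEK293 with AVP came to 0.0300. The shift of all genes by 0.16 and 0.11 exceeds these values. By the mean, gene list glycolysis and hypoxia response, V279del against V2R with AVP came to 0.0200 and gene list fibroblast markers (other cell type), V2R against HEK293 with AVP to -0.0395, and the latter to -0.0344 with an FPKM of at least 5. With the GC trend removed, gene list differentiated epithelial cell markers (other cell type), AVP in V279del cells came to 0.0161, set by MUC1, AVP in V279del cells, at 0.0161. Lists inside the range of random lists as deposited also changed sign with the trend removed. In V279del cells cAMP/CREB targets went from 0.08 to -0.15 and NRF2 targets from -0.02 to 0.29. In V2R cells NF-kB genes went from -0.22 to 0.15, YAP/TEAD targets from -0.01 to 0.19 and epithelial markers from -0.18 to 0.62, and in HEK293 cells epithelial markers from -0.38 to 0.40. These 6 then lay outside that range in the new direction, and other lists changed sign within it. Beyond what each alternative's construction shows, the cause was not tested.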

Other observations

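Cell identity markers were read as values only, and as a whole they do not bear out the HEK293 label. Of the 19 lineage markers, 9 stayed below an FPKM of 1 in all 6 libraries. Of 19 listed neural and renal progenitor markers of HEK293 cells, 10 reached an FPKM of 1, led by KRT18 (63.2 to 184), KRT8 (21.1 to 103), VIM (58.3 to 87.6) and the adhesion gene L1CAM (31.2 to 46.5), while NEFL, NEFM, PAX2 and SOX11 had 0 reads in all 6 libraries. WT1 and CDH2 had at most 1 read, LHX1 at most 3, NCAM1 at most 7 and PAX8 32 to 71. Of 15 differentiated epithelial markers 4 reached an FPKM of 1 (highest 56.6), and of 14 fibroblast markers 6 (highest 380). None of the 15 blood markers (at most 20 reads) and none of the 12 hepatocyte markers (at most 4 reads) reached it, so those lists gave no median. KRT8 and KRT18 were lowest in the V279del library with AVP.

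Mitochondrially encoded genes stood in V279del cells at -0.45 against V2R and -0.33 against HEK293 cells with AVP, and at -0.28 against V2R cells without AVP. Against HEK293 cells without AVP they were at -0.13 (-0.63 to 0.05), within the range of random lists. Replication-dependent histones, whose copies share reads, were at -1.07 and -0.51 in V279del against HEK293 cells with and without AVP, and at -0.46 and -0.23 in V2R against HEK293 cells. Proteasome genes stood at 0.22 and p53 targets at -0.15 in V2R against HEK293 cells without AVP. Constitutive reference genes stayed between -0.19 and 0.09 and the V2R signalling machinery between -0.26 and 0.15 in all 9 comparisons, and neither list left the range of random lists in any of them. Of the 225 pairs of a list and a comparison, 102 lay outside that range, where 3% of simulated unchanged lists of random genes did. Real lists thus left the range often, some of them at small medians. The range takes no account of genes that vary together, so lying outside it does not by itself mark a response.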
